A study of Homo sapiens with 12 samples.

How the data were processed

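RNA-seq libraries from SW48 and OVK18 cells with 3 guides were compared, in 6 groups of 2 libraries. The deposited gene table holds raw counts made with STAR 2.5 on genome build hg19 after bcl2fastq 2.18, per the submitters' processing notes. The authors also deposited a table of non-integer values, read here as FPKM because the counts divided by them grow with transcript length; Cufflinks 2.2.1 is named in the submitters' processing notes, and no header names the unit. Annotation and strand settings are not stated. The count table has 25343 genes and 92 spike-in features, all at 0, which were left out. Gene symbols are as in the table. Of these, 28 had been turned into dates and 4 of them share a symbol, and none of these is named. No coordinates are given, since the annotation at hand is of another build.

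Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM normalisation, filterByExpr with 6 groups (14199 genes tested), 1 coefficient per group, robust quasi-likelihood fit with 6 residual degrees of freedom, and Benjamini-Hochberg adjusted p under 0.05. The WRN-guide effect in a line is the mean of sgWRN2 and sgWRN3 minus sgCh2-2; the difference between lines, each guide alone, the guides against each other and the control libraries of the lines were contrasts of the same fit. Standard errors of log2 fold changes are the fold change over the square root of the F statistic. Levels are means of 2 libraries with SD; intervals of low counts are exact Poisson intervals at 95 percent and, like the floor of 3 counts, cover counting error only. Replicate libraries differed beyond counting error in each group (chi-square per gene 8.25 to 23.5). Groups of 2 are too small for a test of outlying libraries.

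Genes are named by a rule fixed before the data were examined: per line, up to 8 highest and 8 lowest log2 fold changes among genes past the threshold with a mean logCPM of at least 1 and all 4 WRN-guide libraries on 1 side of both controls; 4 and 4 for the difference between lines; up to 4 members of each list by p; and WRN, CDKN1A and MDM2 always. Not every list member so named is reported here. In all 22 gene lists were fixed beforehand and 20 tested with camera from limma 3.58.1 (preset correlation 0.01, minimum 5 members), with an estimated correlation and fry beside it. The list of mitochondrially encoded genes had 0 members in the table, and the leukocyte and endothelial list had 2 tested members. The lists are p53-activated, S phase and DNA replication, mitotic, double-strand break repair, mismatch repair, RecQ helicase, interferon-stimulated, NF-kB target, BCL2 family and caspase, ATF4 and unfolded protein response, cholesterol synthesis, cytosolic ribosomal protein, ribosome biogenesis and MYC target, Wnt target, hypoxia and glycolysis, and immediate-early and MAPK feedback genes, replication-dependent histones, and intestinal, Mullerian and ovarian, and fibroblast markers.

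The steps were tested on simulated counts of the same libraries over 14199 genes with 200 changed genes. The changed genes were drawn from those with a mean of at least 50 counts, so the rates do not cover genes of low counts. These counts held no difference between replicate libraries beyond random spread. For both guides in SW48, 59.7 percent of 1.5-fold and 80.6 percent of 2-fold changes were called, and 4.82 percent of calls were false; for both guides in OVK18 these were 46.3, 89.6 and 6.06 percent. For sgWRN3 in SW48, 46.3 percent of 1.5-fold changes were called. In simulated lists, the raised list was called and 0 of 50 unchanged ones were. Genes were simulated independently of each other, so these lists do not test the preset correlation.

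Alternatives planned beforehand were other scalings (RLE, library size alone, upper quartile), no filter and a mean of 5 CPM, DESeq2 1.42.0, limma-voom, a non-robust fit, only the 6 libraries of a line, a replicate block, limma on the FPKM table with pseudocounts 1 and 0.1, and leaving out each library. After the results were seen, several ways of handling a difference between the A and B libraries were tried: leaving out the 4 sgWRN2 libraries, with and without a replicate block per line, with 1 block shared by both lines, and a library score as a covariate. The score places each library on the A to B difference of sgCh2-2 and sgWRN3 in the other line. In counts simulated with such a shared difference and 1.5-fold changes, the score fit called 43.5 percent of changed genes for both guides in SW48 (8.42 percent of calls false) and 18 percent for sgWRN3 in SW48 (7.69 percent false), whereas the fit without it made no call. With the simulated dispersion at 0.5 times the estimate, false calls were 5.66 to 9.72 percent over the 4 comparisons simulated. With no changed gene, the fit without the sgWRN2 libraries and with a replicate block made 0 false calls in each line, and 1 in each at that lower dispersion. With 1.5-fold changes 7.69 percent of its calls were false in SW48 and 14.6 percent in OVK18, and 11 and 9.93 percent at the lower dispersion. The size of the simulated shared difference was assumed, and its form was the one that a replicate block removes.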

Results

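Messenger RNA levels were measured in 12 libraries from Cas9-expressing SW48 cells, a colorectal cancer line, and OVK18 cells, an ovarian cancer line. Cells carried a control guide against an intergenic site (sgCh2-2) or 1 of 2 guides against WRN (sgWRN2, sgWRN3), and were collected 72 h after transduction. WRN encodes a DNA helicase and exonuclease of the RecQ family. Each of the 6 groups holds 2 libraries, A and B. In SW48 the total counts of A and B were 30752291 and 18301780 with sgCh2-2, 17144701 and 15423162 with sgWRN2, and 16494023 and 16376019 with sgWRN3. In OVK18 they were 26052553 and 32581625 with sgCh2-2, 29651628 and 17600573 with sgWRN2, and 23103268 and 26019108 with sgWRN3. Of 25343 genes, 14199 were tested. Levels are TMM-normalised CPM (counts scaled to library size), given as mean ± SD over 2 libraries, and adjusted p values are from edgeR's quasi-likelihood test unless another tool is named.

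The control libraries were compared first, as background for the difference between the lines. CDX2 and HNF4A, intestinal transcription factors, stood at 87.5 ± 23.4 and 63.7 ± 1.23 CPM in SW48, against 0.0194 ± 0.0275 and 0 CPM in OVK18. CEACAM5, an epithelial surface protein, stood at 53.7 ± 5.43 CPM in SW48 and 0 in OVK18. Of the fibroblast markers, COL3A1, a fibrillar collagen, stood at 436 ± 26.5 CPM in OVK18 and 0.112 ± 0.159 CPM in SW48, and PDGFRA, a growth factor receptor, at 22.4 ± 1.14 and 0 CPM. ACTA2, a smooth muscle actin on that list, was higher in SW48 (29.5 ± 5.59 against 5.25 ± 0.155 CPM). Of the 6 Mullerian and ovarian markers, 4 were higher in SW48: MSLN (37.6 ± 4.43 against 0.0659 ± 0.0382 CPM), PAX8 (4.31 ± 0.518 against 0), HOXA10 (58.9 ± 1.31 against 34.5 ± 2.03) and WFDC2 (0.322 ± 0.00271 against 0). HOXA11 (39.6 ± 2.88 against 15.8 ± 1.08 CPM) and WT1 (0.911 ± 0.194 against 0) were higher in OVK18. The leukocyte and endothelial list had 2 tested members, too few for a test: PTPRC stood at 3.23 ± 0.316 CPM in SW48 and 0.0504 ± 0.0163 in OVK18, and CD68 at 7.39 ± 0.0242 and 5.30 ± 1.19. In all, 9743 genes differed, 4811 higher and 4932 lower in SW48. The floor of 3 counts over the control libraries of a line stands at 0.0603 CPM in SW48 and 0.0517 CPM in OVK18.

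WRN transcript was measured first among the guide effects, since it is the targeted gene. In SW48 it stood at 101 ± 14.4 CPM with sgCh2-2, 35.6 ± 2.19 with sgWRN2 and 49.6 ± 10.3 with sgWRN3. It fell in SW48 by 1.27 on the log2 scale (SE 0.132, adjusted p = 0.00409), and all 4 WRN-guide libraries lay below both control libraries. In OVK18 it stood at 35.9 ± 5.5, 21.5 ± 0.724 and 22.6 ± 0.564 CPM, again with all 4 WRN-guide libraries below both controls. The log2 difference of the WRN transcript in OVK18, -0.71 (SE 0.136), did not pass over all genes (adjusted p = 0.206); it was 0.00577 with DESeq2, and over all alternatives it ran from 2.84e-05 to 1. The WRN difference between the lines was -0.56 (SE 0.195, adjusted p = 1). The WRN transcript in SW48 was -1.13 without SW48 sgCh2-2 replicate B and -1.03 without the sgWRN2 libraries (adjusted p = 1 for the latter). Over the alternatives its adjusted p ran from 6.43e-20 to 1. With the letters A and B as a block as well, the fit without the sgWRN2 libraries gave -1.04 (adjusted p = 2.11e-06). The library score gave -1.02 for sgWRN3 alone (adjusted p = 0.000187). Both of these fits were chosen after the data were seen.

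**Figure D1:**
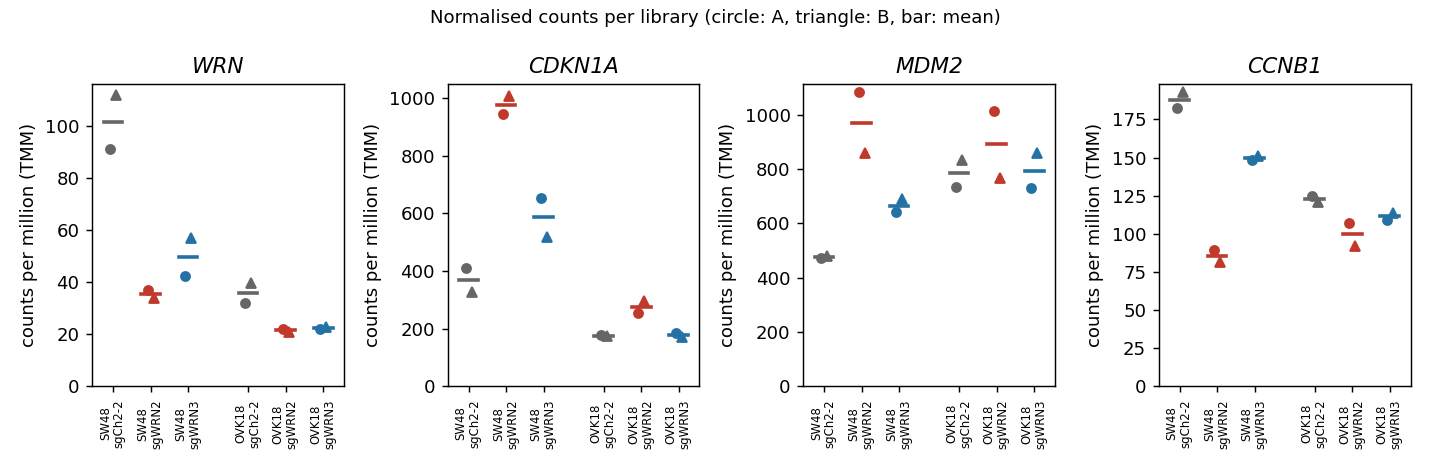
Normalised CPM (vertical axes) of WRN, CDKN1A, MDM2 and CCNB1 in each library, by line and guide; circles are replicate A, triangles replicate B and bars the mean of 2 libraries. WRN means in SW48 were 101 CPM with sgCh2-2, 35.6 with sgWRN2 and 49.6 with sgWRN3.

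With both WRN guides in 1 contrast, genes of cell division fell in SW48 and p53-activated genes rose. Of 50 mitotic genes, 32 fell and none rose, with a median log2 fold change of -0.62. KIF20A, a mitotic kinesin, fell by 0.80 on the log2 scale (SE 0.0967, adjusted p = 0.00507), CCNB1, the mitotic cyclin, by 0.73 (SE 0.084, adjusted p = 0.00507), and CENPA, the centromeric histone, by 0.87 (SE 0.136, adjusted p = 0.0145). Of 49 p53-activated genes, 9 rose and none fell, with a median of 0.31. CDKN1A, a cyclin-dependent kinase inhibitor, stood at 369 ± 60.9 CPM with sgCh2-2, 977 ± 44.2 with sgWRN2 and 587 ± 96.0 with sgWRN3. Over both guides it rose by 1.04 on the log2 scale (SE 0.124, adjusted p = 0.00507). MDM2, the ubiquitin ligase that restrains p53, rose by 0.76 (SE 0.132, adjusted p = 0.0218), GDF15 by 1.09 (SE 0.183, adjusted p = 0.0175) and BTG2 by 0.63 (SE 0.0801, adjusted p = 0.00507). In the test 123 genes changed, 36 higher and 87 lower, against 1113 of 14199 at an unadjusted p under 0.05, where chance alone gives 710. The 710, here and below, assumes evenly spread p values. With sgWRN3 alone the same fit gave 262 in SW48 and 116 in OVK18, so its p values were not evenly spread. A count near or under 710 thus does not show that nothing changed. DESeq2 called 298 genes and limma-voom 147. In edgeR the count was 0 without SW48 sgCh2-2 replicate B (727 at an unadjusted p under 0.05) and 0 without the sgWRN2 libraries (315), or 151 without them and with the letters A and B as a block, a fit chosen after the data were seen. It was 4 without SW48 sgCh2-2 replicate A, 42 and 37 without SW48 sgWRN2 A and B, 51 without SW48 sgWRN3 A and 80 without OVK18 sgWRN3 B.

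Of the genes named by rule in SW48, the 6 with the highest log2 fold changes stood under 1 CPM in its control libraries. NEFM, a neuronal intermediate filament, stood at 0.891 ± 0.190 CPM with sgCh2-2, 27.8 ± 9.42 with sgWRN2 and 2.28 ± 0.576 with sgWRN3 (log2 fold change 3.11, SE 0.309, adjusted p = 0.00409). BEX4 stood at 0.193 ± 0.0439, 5.87 ± 1.80 and 0.570 ± 0.0379 CPM (adjusted p = 0.00616), and CBS, an enzyme of cysteine synthesis, at 0.214 ± 0.150, 3.65 ± 1.01 and 0.689 ± 0.291 CPM (adjusted p = 0.0156). NGFRAP1 stood at 0.0590 ± 0.0071 CPM in the controls, where it held 3 counts in all (interval 0.0124 to 0.176 CPM), against 1.52 ± 0.251 with sgWRN2 and 0.390 ± 0.0393 with sgWRN3 (adjusted p = 0.00507). VASH1 and ANKRD18B also rose (adjusted p = 0.0252 and 0.0467). In the OVK18 controls NGFRAP1 stood at 183 ± 0.314, CBS at 171 ± 6.59, VASH1 at 63.8 ± 5.28 and BEX4 at 30.03 ± 0.568 CPM. The rule's mean logCPM of at least 1 was taken over all 12 libraries. Genes this low in SW48 could thus pass it mainly by being high in OVK18, so these levels are partly set by the rule. Among better expressed genes, ABCA12, a lipid transporter, rose by 1.14 (SE 0.135) and FLG-AS1 by 1.17 (SE 0.137), the latter uncertain because it is antisense to another gene. Beside WRN, CENPA, KIF20A and CCNB1, the genes with the largest falls were CDCA3 (-0.83), NEK2 (-0.77), TRAIP (-0.76) and FIGNL1 (-0.76).

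Lists fixed before the data were examined were each tested in SW48 with camera. Mitotic genes were lower (adjusted p = 2.53e-126; 0.000973 with an estimated correlation), and 48 of 50 fell when adjusted over the list alone. S phase and DNA replication genes were lower (median -0.43, adjusted p = 5.81e-60; 0.00248 with an estimated correlation): 11 of 49 fell, 42 adjusted over the list alone, among them RRM2 (-0.64), GINS2 (-0.61) and E2F2 (-0.64). The p53-activated genes were higher (adjusted p = 1.44e-35; 0.00323 with an estimated correlation), with 26 of 49 risen when adjusted over the list alone. Double-strand break repair genes were lower (median -0.26, adjusted p = 1.38e-16; 0.0416 with an estimated correlation): FANCI fell (-0.56, adjusted p = 0.0154), and 16 of 46 fell adjusted over the list alone. RecQ helicases were lower (median -0.39 over 5 genes, adjusted p = 9.03e-10; 0.00323 with an estimated correlation), where WRN alone passed over all genes and 3 passed adjusted over the list alone. This list holds WRN, the target of the guides, and was not tested without it. Its calls, here and below, are thus partly set by the design. Without the sgWRN2 libraries, camera with an estimated correlation lost the calls of double-strand break repair genes (median -0.08348, adjusted p = 0.392) and RecQ helicases (-0.1852, adjusted p = 0.0538). It kept those of mitotic, p53-activated, and S phase and DNA replication genes (adjusted p = 0.0357, 0.0357 and 0.048).

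Calls of 6 further SW48 lists were lost with an estimated correlation. Mismatch repair genes were lower (median -0.05 over 7 genes, adjusted p = 0.00897; adjusted p = 0.487 with an estimated correlation): EXO1 fell (-0.56, adjusted p = 0.0196), and 2 fell adjusted over the list alone. NF-kB target genes were higher (median 0.20 over 12 genes, adjusted p = 0.0103; adjusted p = 0.13 with an estimated correlation) and 0 members passed, also adjusted over the list alone. ATF4 and unfolded protein response genes were lower (median -0.09 over 24 genes, adjusted p = 0.0235; adjusted p = 0.659 with an estimated correlation), where ASNS, asparagine synthetase, fell (-0.48, adjusted p = 0.0175) and 3 fell adjusted over the list alone. Cholesterol synthesis genes were lower (median -0.14 over 25 genes, adjusted p = 0.00121; adjusted p = 0.258 with an estimated correlation), with 0 members past the threshold and 1 adjusted over the list alone. Cytosolic ribosomal proteins were higher (median 0.13, adjusted p = 2.98e-08; adjusted p = 0.369 with an estimated correlation), with 0 of 55 past the threshold either way. Replication-dependent histones, a check of poly-A selection, were higher (median 0.33 over 15 genes, adjusted p = 0.000762; adjusted p = 0.214 with an estimated correlation), with 0 past the threshold and 3 adjusted over the list alone. No call was made in SW48 for interferon-stimulated genes (adjusted p = 0.676), BCL2 family and caspases (0.919), ribosome biogenesis and MYC target genes (0.7), Wnt target genes (0.722), hypoxia and glycolysis genes (0.624), immediate-early and MAPK feedback genes (0.53), intestinal epithelial markers (0.952), Mullerian and ovarian markers (0.624) or fibroblast markers (0.392). One Wnt target, CCND1, rose (0.42, adjusted p = 0.0355). Median, mean and test differed in sign for the interferon-stimulated, BCL2 family and caspase, Wnt target and intestinal lists. Leaving out 1 SW48 library ended the call of mismatch repair genes (sgCh2-2 B, adjusted p = 0.126; sgWRN2 B, 0.0664, with a median of 0.002506; sgWRN3 A, 0.134) and of ATF4 and unfolded protein response genes (sgCh2-2 A, 0.122; sgWRN2 B, 0.115; sgWRN3 B, 0.186). It also ended that of histones (sgCh2-2 B, 0.156; sgWRN3 A, 0.0719) and of NF-kB target genes (sgCh2-2 B, 0.379; sgWRN2 A and B, 0.144 and 0.115; sgWRN3 A and B, 0.155 and 0.0605; OVK18 sgWRN2 B, 0.117).

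**Figure D2:**
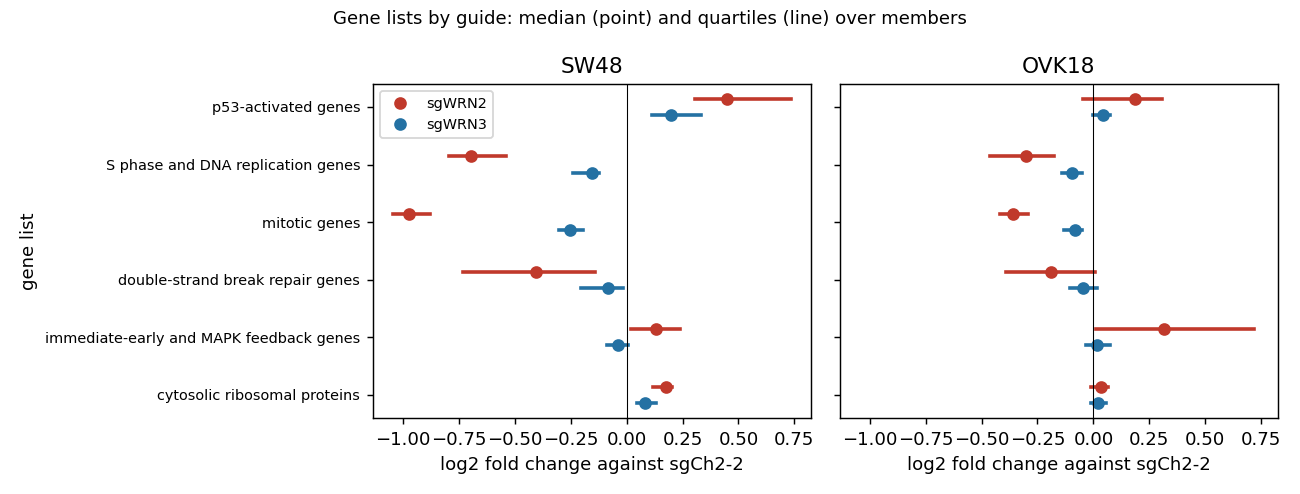
Median log2 fold change against sgCh2-2 (horizontal axis; points) and quartiles over members (lines) of 6 gene lists, by guide and line. With sgWRN2 in SW48 the mitotic median was -0.97 and the p53-activated median 0.45.

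In OVK18, 4 genes changed with both WRN guides in 1 contrast. NEFM rose from 0.640 ± 0.0290 CPM with sgCh2-2 to 28.2 ± 2.86 with sgWRN2 and 1.99 ± 0.592 with sgWRN3 (log2 fold change 3.55, SE 0.314, adjusted p = 0.00142). IFT57, a component of cilia transport, stood at 0.202 ± 0.0653, 4.16 ± 0.308 and 0.344 ± 0.117 CPM (2.52, SE 0.321, adjusted p = 0.0222). EGR1, an immediate-early transcription factor, stood at 67.5 ± 1.17, 200 ± 11.2 and 71.2 ± 2.40 CPM (0.82, SE 0.0796, adjusted p = 0.00195). RND3 fell from 1.77 ± 0.303 to 0.439 ± 0.0761 with sgWRN2 and 0.446 ± 0.138 with sgWRN3 (-2.004, SE 0.262, adjusted p = 0.0222). CDKN1A stood at 176 ± 4.01, 274 ± 29.5 and 180 ± 10.7 CPM (0.33, adjusted p = 1) and MDM2 at 784 ± 69.8, 892 ± 175 and 794 ± 91.1 CPM (0.10, adjusted p = 1). These 4 calls, 3 higher and 1 lower, compare with 573 genes at an unadjusted p under 0.05 (710 by chance alone), 30 calls by DESeq2 and 3 by limma-voom. In edgeR 0 genes were called without OVK18 sgCh2-2 replicate A, without its replicate B or without the sgWRN2 libraries (298, 303 and 124 at an unadjusted p under 0.05), and 2 without OVK18 sgWRN2 A or sgWRN3 B.

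Cell division genes were lower in OVK18 as lists, though 0 members passed over all genes in edgeR. Mitotic genes were lower in 50 of 50 cases (median -0.22, adjusted p = 8.6e-24; 0.0315 with an estimated correlation), and S phase and DNA replication genes in 49 of 49 (median -0.21, adjusted p = 2.44e-20; 0.0315 with an estimated correlation). Neither list had a member past the threshold adjusted over the list alone. The mitotic members with the smallest p were AURKA (-0.26), GTSE1 (-0.30), ANLN (-0.31) and CENPA (-0.43), all at adjusted p = 1. With sgWRN3 alone in OVK18 the calls of both lists were lost with an estimated correlation: the mitotic median was -0.08 (adjusted p = 1.04e-07; adjusted p = 0.358 with an estimated correlation) and the S phase and DNA replication median -0.10 (adjusted p = 4.95e-08; adjusted p = 0.321 with an estimated correlation). Immediate-early and MAPK feedback genes were higher with both guides in 1 contrast, but not without the sgWRN2 libraries, where the median was 0.01694 (adjusted p = 0.123). Over both guides the list was higher (median 0.20 over 22 genes, adjusted p = 4.67e-13; 0.0315 with an estimated correlation): EGR1 rose, and 3 rose adjusted over the list alone, while EGR3 (1.11) and EGR2 (1.25) had adjusted p = 0.0877 and 0.182.

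Calls of 7 other OVK18 lists were lost with an estimated correlation. The p53-activated genes were higher (median 0.12, adjusted p = 1.08e-05; adjusted p = 0.152 with an estimated correlation), with 0 of 49 past the threshold and 1 adjusted over the list alone; PLK2 stood at 0.60 (adjusted p = 0.0895). Double-strand break repair genes were lower (median -0.10, adjusted p = 3.71e-05; adjusted p = 0.268 with an estimated correlation) and RecQ helicases too (median -0.20, adjusted p = 0.00133; adjusted p = 0.0549 with an estimated correlation), with 0 and 1 members fallen adjusted over the list alone. ATF4 and unfolded protein response genes were lower (median -0.15, adjusted p = 0.000132; adjusted p = 0.37 with an estimated correlation), as were hypoxia and glycolysis genes (median -0.04, adjusted p = 0.0132; adjusted p = 0.243 with an estimated correlation). Ribosome biogenesis and MYC target genes were higher (median 0.05, adjusted p = 0.0238; adjusted p = 0.514 with an estimated correlation). Replication-dependent histones were higher (median 0.39, adjusted p = 9.97e-09; adjusted p = 0.0549 with an estimated correlation), with 2 of 15 risen adjusted over the list alone. No call was made in OVK18 for mismatch repair genes (adjusted p = 0.459), interferon-stimulated genes (0.0833), NF-kB target genes (0.629), BCL2 family and caspases (0.629), cholesterol synthesis genes (0.882), cytosolic ribosomal proteins (0.375), Wnt target genes (0.872), intestinal epithelial markers (0.629), Mullerian and ovarian markers (0.768) or fibroblast markers (0.882). Median, mean and test differed in sign for the mismatch repair, NF-kB target and fibroblast lists. Without the sgWRN2 libraries the ATF4 and unfolded protein response list was higher (median 0.07703, adjusted p = 0.000279; adjusted p = 0.581 with an estimated correlation), the MYC target list had a median of -0.02095 and the hypoxia list one of 0.01714. Without them the calls also ended for p53-activated genes (median 0.04387, adjusted p = 0.0664), double-strand break repair genes (-0.04602, adjusted p = 0.0647) and histones (0.1485, adjusted p = 0.123) in OVK18. Leaving out 1 OVK18 library ended the call of ATF4 and unfolded protein response genes (sgCh2-2 A, adjusted p = 0.854; sgWRN3 B, 0.0818), hypoxia and glycolysis genes (sgCh2-2 A, 0.456; sgWRN2 A, 0.246), MYC target genes (sgCh2-2 B, 0.546; sgWRN3 A, 0.0935) and RecQ helicases (sgWRN2 A, 0.0748).

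The difference between the lines was tested directly. The log2 fold change was higher in SW48 for NGFRAP1, by 3.64 (SE 0.414, adjusted p = 0.0211), and for RND3, by 2.14 (SE 0.304, adjusted p = 0.0494), whose values were 0.14 in SW48 and -2.004 in OVK18. NGFRAP1 held 3 counts in the SW48 controls, so its fitted difference depends on the prior count. IFT57 and EGR1 rose more in OVK18, with differences of -2.47 (SE 0.342, adjusted p = 0.0494) and -0.87 (SE 0.108, adjusted p = 0.0256). The differences for CDKN1A (0.70, adjusted p = 0.897) and MDM2 (0.65, adjusted p = 1) did not pass. As lists, mitotic genes fell more in SW48 (median difference -0.39, adjusted p = 8.79e-58; 0.00996 with an estimated correlation), and p53-activated genes rose more (0.24, adjusted p = 1.43e-19; 0.0254 with an estimated correlation). S phase and DNA replication genes (-0.22; 0.0368 with an estimated correlation), RecQ helicases (-0.25; 0.0404 with an estimated correlation) and immediate-early and MAPK feedback genes (-0.11; 0.0403 with an estimated correlation) had lower log2 fold changes in SW48 than in OVK18. Without the sgWRN2 libraries the calls ended for RecQ helicases (-0.1026, adjusted p = 0.0991) and immediate-early and MAPK feedback genes (-0.07181, adjusted p = 0.0926). Those of mitotic and p53-activated genes (adjusted p = 0.224 for both with an estimated correlation) and of S phase and DNA replication genes (adjusted p = 0.391 with an estimated correlation) were then lost with an estimated correlation. The 4 genes called, 2 in each direction, compare with 391 at an unadjusted p under 0.05, fewer than the 710 of chance alone. DESeq2 called 11 genes and limma-voom 4. In edgeR 0 genes were called without the sgWRN2 libraries (163 at an unadjusted p under 0.05) or without any 1 of 8 libraries (282 to 469): sgCh2-2 A or B of either line, SW48 sgWRN3 A or B, SW48 sgWRN2 A, or OVK18 sgWRN3 B. The count was 1 without SW48 sgWRN2 B or OVK18 sgWRN3 A and 2 without OVK18 sgWRN2 B.

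Each guide was then compared with the control on its own, since a single guide can have effects of its own. In SW48, sgWRN2 changed 437 genes, 160 higher and 277 lower: 45 of 50 mitotic genes and 34 of 49 S phase and DNA replication genes fell, and 19 of 49 p53-activated genes rose (adjusted p = 0.000744, 0.0017 and 0.00514 with an estimated correlation). CDKN1A rose by 1.40 (SE 0.139) and MDM2 by 1.03 (SE 0.149). CD55, a complement regulator, rose with sgWRN2 from 626 ± 55.4 to 1439 ± 109 CPM (adjusted p = 0.000257), and stood at 734 ± 79.9 with sgWRN3. MKI67, a proliferation marker, fell by 1.10 (adjusted p = 0.000227). CD55 and MKI67 were chosen after their values were seen. With sgWRN3 in SW48 edgeR called 0 genes (262 at an unadjusted p under 0.05, against 710 by chance alone), limma-voom 0, DESeq2 9, limma on the FPKM values 3 and edgeR without a filter 22, 20 higher and 2 lower. In fits chosen after the data were seen, edgeR called 6 genes with sgWRN3 in SW48 with a library score as a covariate, and 151 without the sgWRN2 libraries and with the letters A and B as a block. As lists with sgWRN3 in SW48, mitotic genes were lower (median -0.25, adjusted p = 6.83e-38; 0.0125 with an estimated correlation) and p53-activated genes higher (0.20, adjusted p = 2.9e-26; 0.0125 with an estimated correlation). The difference between sgWRN2 and sgWRN3 in SW48 passed for 134 genes, 41 higher and 93 lower with sgWRN2. The sgWRN2 count was 195 without SW48 sgCh2-2 B and 167 and 148 without SW48 sgWRN2 A and B; that between the guides was 3 and 17 without sgWRN2 A and B, and 77 and 8 without sgWRN3 A and B.

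In OVK18, sgWRN2 changed 113 genes, 76 higher and 37 lower. EGR2 and EGR3, transcription factors of the EGR1 family, rose by 2.14 and 1.67 on the log2 scale (adjusted p = 0.00212 for both), and TXNIP, a regulator of glucose uptake, rose by 1.33 (adjusted p = 0.000237). TIMP1, a metalloproteinase inhibitor, rose from 32.8 ± 5.13 to 93.6 ± 10.9 CPM (adjusted p = 0.00229). Immediate-early and MAPK feedback genes were higher with sgWRN2 (median 0.32, adjusted p = 1.84e-14; 0.0295 with an estimated correlation), and 4 of 22 rose. TXNIP, TIMP1, EGR2 and EGR3 were chosen for this comparison after their values were seen. With sgWRN3 in OVK18 edgeR called 0 genes (116 at an unadjusted p under 0.05, against 710 by chance alone), limma-voom 0, limma on the FPKM values 0, DESeq2 1 and edgeR without a filter 2. In the same fits chosen after the data were seen, edgeR called 1 gene with the library score and 12 with the block. The difference between the guides in OVK18 passed for 106 genes, 62 higher and 44 lower with sgWRN2. Most of these calls were lower in some fits: without a filter 188 were higher and 251 lower with sgWRN2, and 207 and 311 between the guides, and without OVK18 sgWRN2 A 54 were higher and 88 lower with sgWRN2. The sgWRN2 count was 18 and 23 without OVK18 sgCh2-2 A and B, 41 without OVK18 sgWRN2 B, 72 and 71 without SW48 sgWRN2 A and B, and 75 and 72 without OVK18 sgWRN3 A and B. The count between the guides was 11 and 27 without OVK18 sgWRN3 A and B, 52 without OVK18 sgWRN2 B, 70 without either OVK18 sgCh2-2 library, and 67 and 60 without SW48 sgWRN2 A and B.

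Genes called in both lines were then counted. NEFM alone rose in both lines with both guides in 1 contrast, where independent lists give 0.00761 genes (one-sided exact hypergeometric test, p = 0.00759), and 0 genes called in edgeR fell in both. With sgWRN2 alone 22 genes rose in both lines, among them AGO2, LAMC1, BRAF and PLK2, where independent lists give 0.856 (one-sided exact hypergeometric test, p = 1.36e-25). A further 16 fell in both, among them CDC6, MCM3 and TRIP13, where independent lists give 0.722 (p = 2.55e-18 by the same exact test); these genes were chosen after their values were seen. These exact tests take genes as independent and the libraries of the 2 lines as unrelated. Genes are not independent replicates, and the B minus A differences of sgWRN2 correlated between the lines (0.473). Their p values thus cannot be read at face value. Of the 123 genes called in SW48, 113 had the same sign in OVK18, with a median log2 change of 0.22 in the SW48 direction against 0.616 in SW48. With both lines fitted together 141 genes changed, 40 higher and 101 lower, among them 31 of 50 mitotic and 13 of 49 S phase and DNA replication genes. Without the sgWRN2 libraries edgeR called 0 genes (282 at an unadjusted p under 0.05). The count was 4 and 15 without OVK18 sgCh2-2 A and B, 85 and 13 without SW48 sgCh2-2 A and B, 71 and 41 without SW48 sgWRN2 A and B, and 93 without SW48 sgWRN3 A. It was 67 and 48 without OVK18 sgWRN3 A and B, and 244 without OVK18 sgWRN2 A.

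The fold changes of the guides were correlated across genes, which are not independent replicates. In SW48 sgWRN2 and sgWRN3 gave Pearson's r of 0.514, where unchanged groups simulated against the same controls gave a median of 0.54, and a covariance of 0.0879 against 0.0661. In OVK18 r was 0.305 against a simulated 0.495, and the covariance 0.041 against 0.0527. The controls were not split between the guides. In neither line did r exceed the simulated median. The simulation drew libraries independently, whereas the B minus A differences of sgCh2-2 and sgWRN3 correlated within lines (0.518 in SW48, 0.503 in OVK18). The simulated r and covariance thus do not stand for the shared controls alone. The comparison of r therefore decides nothing on the likeness of the guides. The covariance differed from the simulated median by 0.0219 in SW48, where the highest simulated value was 0.0684, and by -0.0117 in OVK18. Between the lines, which share no controls, r was 0.204 for sgWRN2 (simulated median 0.000481) and 0.0228 for sgWRN3 (simulated highest value 0.0274). The simulation takes the libraries of the 2 lines as independent, whereas the B minus A differences of sgWRN2 correlated between the lines (0.473), so the simulation does not cover a difference between libraries that the lines share. Spearman's rho between the lines was 0.295 for sgWRN2 and 0.0921 for sgWRN3.

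The A and B libraries differed in a way that ran through both lines. The B minus A differences of sgCh2-2 and sgWRN3 followed GC content across genes, with Spearman's rho of -0.729 in SW48 and -0.685 in OVK18, and those of sgWRN2 went the other way (0.584 and 0.734). The sgWRN2 libraries against the controls had rho of -0.00745 and 0.173 with GC content.

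**Figure D3:**
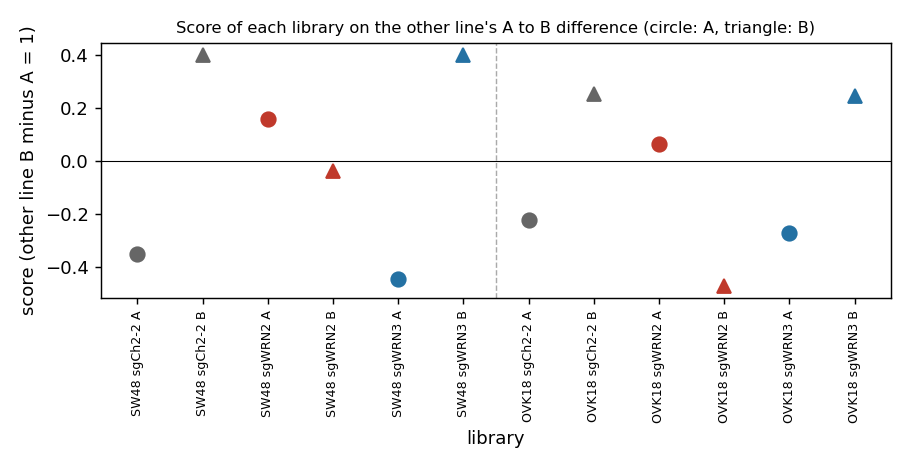
Score of each library on the B minus A difference of sgCh2-2 and sgWRN3 in the other line (vertical axis, no unit, where 1 is the full difference), a measure chosen after the data were seen; circles are replicate A, triangles replicate B, colours the guides. In SW48 the B libraries of sgCh2-2 and sgWRN3 scored 0.398 and 0.399, against -0.352 and -0.446 for A.

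**Figure D4:**
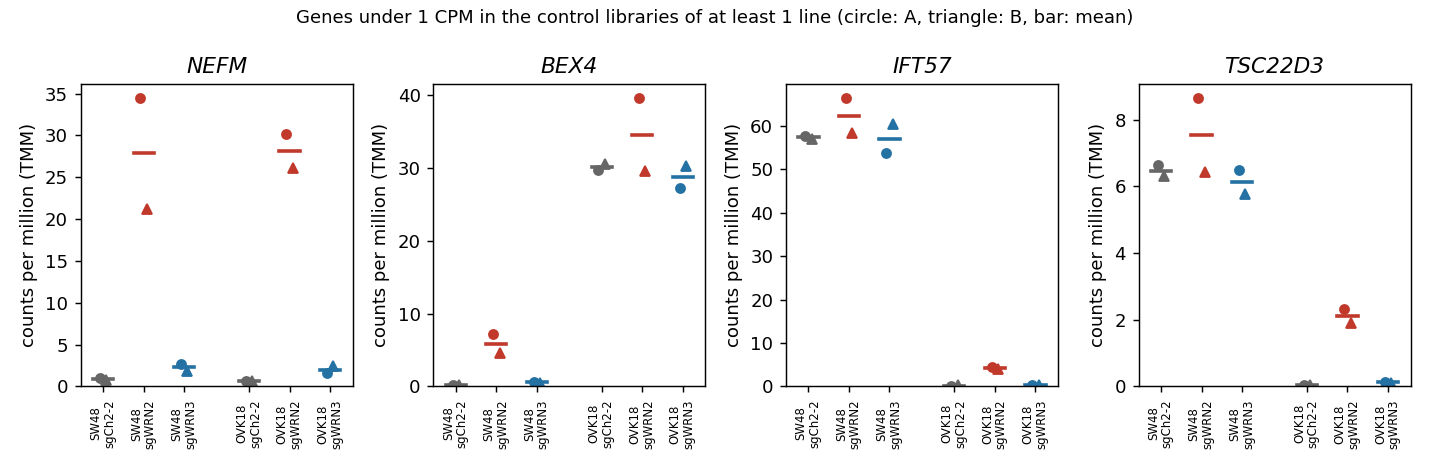
Normalised CPM (vertical axes) of NEFM, BEX4, IFT57 and TSC22D3 in each library, by line and guide; circles are replicate A, triangles replicate B and bars the mean of 2 libraries. NEFM means were 27.8 CPM with sgWRN2 in SW48 and 28.2 in OVK18, against 0.891 and 0.640 in the controls.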

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

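Of the tests below, the count of splits with 1 coefficient for both guides and the test of GC content were set before their results were seen, and the others were chosen afterwards.

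Direct tests of the difference between the lines picked out 4 genes and 9 lists. The log2 fold change in SW48 minus that in OVK18 was 3.64 for NGFRAP1, 2.14 for RND3, -2.47 for IFT57 and -0.87 for EGR1. The difference of list medians was 0.24 for p53-activated genes, -0.22 for S phase and DNA replication genes, -0.39 for mitotic genes, -0.14 for double-strand break repair genes and -0.25 for RecQ helicases. It was 0.15 for NF-kB target genes, -0.11 for cholesterol synthesis genes, 0.10 for cytosolic ribosomal proteins and -0.11 for immediate-early and MAPK feedback genes. Some of these depended on the libraries in the fit, for NF-kB target genes and cytosolic ribosomal proteins on more than 1. Without OVK18 sgCh2-2 A the median was 0.01992 for NF-kB target genes and 0.01655 for cytosolic ribosomal proteins. Without SW48 sgCh2-2 B these medians were 0.09876 and 0.04294. Without OVK18 sgCh2-2 B the median was -0.04708 for cholesterol synthesis genes. With an estimated correlation the difference was lost for double-strand break repair genes (adjusted p = 0.193), NF-kB target genes (adjusted p = 0.193), cholesterol synthesis genes (adjusted p = 0.287) and cytosolic ribosomal proteins (adjusted p = 0.402).

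Genes under 1 CPM in the control libraries rose with sgWRN2, 52 in SW48 and 30 in OVK18. RNA or reads from the other line would raise its abundant genes by 1 common share, whose upper bound was 0.0655 percent in SW48 and 0.0237 percent in OVK18. In both lines 100 percent of the genes of the pattern lay above it, which was nearly fixed, since they were picked for their rise. The share itself came from 219 genes in SW48 and 203 in OVK18, under 0.3 CPM in the line's controls and over 30 CPM in the other's. Its median was 0.0467 percent in SW48 and 0.0171 percent in OVK18. Handling of the sgWRN2 libraries alike in both lines stays open. Of 10 genes per line under 1 CPM in the controls of both lines, 70 percent also rose in the other line. That share lay between the bounds set. The same genes make up the 70 percent from either line, so this is 1 result. Both lines had the same guide, so a shared rise cannot tell handling from an effect of sgWRN2. The other genes of the pattern stood at 1 CPM or more in the other line's controls and were left out of this test. A response to WRN loss that is stronger with sgWRN2 may also account for it: sgWRN3 showed a median fraction of 0.0581 of the rise in SW48 and 0.0486 in OVK18, above 0 and below the fractions of the mitotic fall (0.329 and 0.264) and of the fall of the WRN transcript (0.787 and 0.926). The genes of the pattern were picked for low controls and for their rise with sgWRN2, and the mitotic genes were not. Their fractions are thus not like for like, and the comparison decides nothing. An effect of sgWRN2 on another site was not tested.

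Immediate-early and MAPK feedback genes were higher with sgWRN2 in OVK18, with a median of 0.32. Handling of the sgWRN2 libraries alike in both lines stays open: in SW48 the median was 0.13 and the upper quartile 0.24, above the lower quartile of 0.01 in OVK18. Against it stand that the list was not called in SW48 (adjusted p = 0.213) and that EGR1, EGR2 and EGR3 had 0.07, 0.16 and -0.21 there, against 1.56, 2.14 and 1.67 in OVK18, though these genes were picked for their rise. A response to WRN loss graded by guide stays open as well: sgWRN3 showed a fraction of 0.0784, with an interval from -0.0822 to 0.34 that reaches the fraction of the mitotic genes (0.264).

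No gene was called with sgWRN3 in SW48 by edgeR (262 at an unadjusted p under 0.05; limma-voom 0, DESeq2 9, edgeR without a filter 22), and the A and B libraries of sgCh2-2 and sgWRN3 differed alike in both lines. The difference followed GC content of the transcripts: across genes, which are not independent replicates, Spearman's rho was -0.729 in SW48 and -0.685 in OVK18, for 94.6 percent of genes with a GC value. With the library score as a covariate, 6 genes were called with sgWRN3 in SW48 (WRN, CDKN1A, GDF15, PLK2, BTG2 and HES2), fewer than the 10 set as the bound; without the sgWRN2 libraries 151 were called with the letters as a block, and 176 with 1 block shared by both lines, against 0 without a block, so a shared difference between libraries may hide calls but is not settled. Of those 151 genes, 149 had the same sign with sgWRN2 in the main fit and 84 were also called there, though the guides share their controls. WRN, CDKN1A and MDM2 had the smallest adjusted p in the block fit (2.11e-06, 2.77e-06 and 0.000194 in edgeR). Among the 151 genes, 136 changed by under 1.5-fold, which goes against too few libraries as the whole cause only if the block fit is sound. That fit has fewer residual degrees of freedom than the main one. Its false calls in simulated counts were at most 1 with no change, and 7.69 and 11 percent of calls in SW48 with 1.5-fold changes. The simulated A to B difference had the form that the block removes, so low false calls were partly built in. Too few libraries as the whole cause is thus not settled.

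Other splits of the libraries within lines were counted for the fit of both lines. With 1 coefficient for both guides, the real split called 1 gene and 18 of 100 splits called as many, the highest other 987. Most of these splits set both sgWRN2 libraries of 1 line apart, with 21 to 59 genes called. Such splits keep whatever sets the sgWRN2 libraries apart, so they do not show what chance alone gives. Chance is neither shown nor excluded for that count. With 1 coefficient per guide, chosen after that result, the real split called 141 genes and 4 of 100 splits called as many, the highest other 1326. That share is under 0.05, but 100 of 2025 possible splits were drawn and the version was chosen after the first, so it does not settle that chance is excluded. Splits that call many genes point to a structure of the samples: of those drawn, the highest in both versions set apart the B libraries of sgCh2-2 and sgWRN3, and a split outside those drawn, which set the sgWRN2 libraries apart in both lines, called 1504 genes with 1 coefficient for both guides.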

How the results depend on the processing

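The fits without the sgWRN2 libraries and the library score were chosen after seeing the data; the others were planned. Of the alternative values of counts and of WRN, 300 stayed within 1.5 times or on their side of the threshold, 131 moved, 5 passed it and 2 lost it; named genes kept their call in 473 and lost it in 220, list calls changed in 82 (lost) and 21 (gained), and the cause was not tested.

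A replicate block (A and B; the labels do not say what the letters share) called 28 genes in SW48 (17 higher, 11 lower; 36 and 87 without it), 2 in OVK18, 9 in both lines (8 higher, 1 lower; 40 and 101 without it), 0 for the difference between lines (edgeR, 356 at an unadjusted p under 0.05; DESeq2 without a block 11), 265 and 38 with sgWRN2 in SW48 and OVK18, and 43 and 31 between guides. Same-letter libraries correlated in their deviations between sgCh2-2 and sgWRN3 (0.413 in SW48, 0.39 in OVK18). They did not with sgWRN2 (-0.226 to 0.00693), so not every pair of groups deviated together. The block takes the A to B difference as the same for every guide. Against GC content, however, the B minus A differences of sgWRN2 had Spearman's rho of 0.584 in SW48 and 0.734 in OVK18. Those of sgCh2-2 and sgWRN3 had -0.729 and -0.685. The block thus cannot remove both, and its lower counts do not show that a replicate difference made the calls lost with it.

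Leaving out 1 library gave 0 to 174 genes in SW48, 0 to 4 in OVK18, 4 to 244 in both lines, 0 to 3 for the difference, 148 to 520 and 18 to 142 with sgWRN2 in SW48 and OVK18, 3 to 176 and 11 to 100 between guides, 8569 to 10116 between lines, and 0 to 1 shared. WRN ranged from -1.42 to -1.13 in SW48 and -0.85 to -0.53 in OVK18. A group left with 1 library is assumed to vary like the others.

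Without a filter, edgeR called 292 (SW48), 30 (OVK18), 381 (both), 17 (difference), 688 and 439 (sgWRN2), 22 and 2 (sgWRN3), 334 and 518 (guides) and 6 shared, and the WRN transcript in OVK18 passed (-0.70, adjusted p = 0.000215). DESeq2 called 298, 30, 367, 11, 709 and 430, 9 and 1, 298 and 530, and 12 shared, with WRN past the threshold in OVK18 (-0.70, adjusted p = 0.00577). Only the 6 libraries of a line gave 44 (SW48), 1 (OVK18), 30 (OVK18 sgWRN2), and 34 and 25 (guides). RLE size factors gave 2 genes for the difference, as did the strict filter; library size alone gave 213 (both) and 2 shared, upper quartile 2 shared, limma-voom 161 (OVK18 guides). The FPKM table gave 213 (both) and 3 (SW48 sgWRN3) with pseudocount 1, and 10 (OVK18), 229 (both), 9 (difference), 4 (SW48 sgWRN3) and 2 shared with 0.1. RLE also moved the OVK18 sgWRN2 split from 76 higher and 37 lower to 78 and 20, and that between guides from 62 and 44 to 79 and 33; without a filter these were 188 and 251, and 207 and 311.

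Without the sgWRN2 libraries, edgeR called 0 genes in SW48, OVK18, both lines and the difference (315, 124, 282 and 163 at an unadjusted p under 0.05; no other tool was run on these libraries) and 0 shared, 4 lists were called in OVK18, and the WRN transcript in SW48 was -1.03 (adjusted p = 1). With a replicate block as well, 151 genes were called in SW48, 12 in OVK18, 62 in both and 3 shared. WRN then passed in SW48 (-1.04, adjusted p = 2.11e-06) and in OVK18 (-0.67). With 1 block shared by both lines the counts were 176, 4, 67 and 2, and WRN in OVK18 was -0.67 (adjusted p = 2.84e-05). The library score called 686 (SW48), 36 (OVK18), 858 (both), 18 (difference), 1600 and 1376 (sgWRN2), 6 and 1 (sgWRN3), 715 and 1593 (guides) and 18 shared, and WRN in OVK18 was -0.67 (adjusted p = 0.00282).

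With an estimated correlation 5, 3 and 5 lists were called in SW48, OVK18 and the difference, and with fry 6, 5 and 5; leaving out 1 library gave 8 to 11 in each. Lists that turned direction: cytosolic ribosomal proteins in OVK18 without its sgCh2-2 replicate B (-0.0521; leaving out 1 library gave up to 0.1004); without the sgWRN2 libraries, ATF4 and unfolded protein response genes in OVK18 (0.07703) and between lines (-0.2388), ribosome biogenesis and MYC target genes (-0.02095) and hypoxia and glycolysis genes (0.01714) in OVK18. Calls lost without those libraries: in SW48 NF-kB target genes (0.09608, adjusted p = 0.234) and histones (0.09018, 0.122); between lines double-strand break repair (-0.04226, 0.0585), RecQ (-0.1026, 0.0991), NF-kB target (0.1301, 0.0926) and immediate-early genes (-0.07181, 0.0926). The cause was not tested. No scaling moved the median of all genes by over 0.1.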

Other observations

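The tests of this part were chosen after the results were seen.

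Some genes of the unfolded protein response, chosen after their values were seen, were lower with sgWRN2 than with sgWRN3 in OVK18. HERPUD1, an endoplasmic reticulum stress protein, had a log2 fold change of -1.003 with sgWRN2 (SE 0.151, adjusted p = 0.00991), and it lay 1.23 below its sgWRN3 level (log2 difference -1.23, SE 0.151, adjusted p = 0.0044). HSPA5, the main chaperone of the endoplasmic reticulum, differed by -0.93 between the guides (SE 0.155, adjusted p = 0.0165), MANF by -1.17 (adjusted p = 0.0132), CRELD2 by -1.05 (adjusted p = 0.0354) and XBP1 by -0.75 (adjusted p = 0.0367). The ATF4 and unfolded protein response list was lower with sgWRN2 than with sgWRN3 (median -0.49, adjusted p = 3.33e-15; adjusted p = 0.117 with an estimated correlation): 4 of 24 members fell, 16 adjusted over the list alone. With sgWRN3 against the control in OVK18 the list was higher (median 0.08, 20 of 24 members above 0, adjusted p = 0.000133; adjusted p = 0.516 with an estimated correlation), and 0 members passed in edgeR (116 genes at an unadjusted p under 0.05; limma-voom 0, DESeq2 1). Without the sgWRN2 libraries and with the letters A and B as a block, CRELD2 (0.57, adjusted p = 0.00179), HYOU1 (0.39, adjusted p = 0.0122), HSPA5 (0.32, adjusted p = 0.0129) and MANF (0.36, adjusted p = 0.02) passed with sgWRN3 in OVK18, in a fit with 14.6 percent of calls false in simulated counts with 1.5-fold changes in OVK18. With the library score WRN alone was called with sgWRN3 in OVK18, and 1 block shared by both lines called 4 genes.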
